A study of Mus musculus with 33 samples.

How the data were processed

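Cells were sorted from kidney and spleen of 10-week-old mice with Cre in both copies of Clec9a and the YFP reporter in both copies of Rosa26, on a C57BL/6 background. Kidney cells were CD45+ Ly6C- MHCII+ before the gates named in the text. Per the labels, cells were sorted into lysis buffer, RNA was isolated with the PicoPure kit, amplified to cDNA with a SMARTseq kit that starts from polyA RNA, and made into libraries without strand information with the MicroPlex kit. The 33 libraries form 9 groups: RPM, spleen cDC2, spleen cDC1, F4/80hi YFP- and F4/80hi YFP+ with 3 libraries each, CD11bhi YFP- with 2, CD11bhi YFP+ and kidney cDC2 with 5 each, and kidney cDC1 with 6. Replicate numbers follow the order of the deposited samples.

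The authors' processing used STAR and RSEM on mm10, per the submitters' processing notes, without stated versions. Read counts per gene are the authors' STAR output, deposited per library for 24054 gene symbols, with reads that are unmapped, multimapping, outside genes or ambiguous counted apart. Expected counts per gene are the authors' RSEM output, per the file headers. TPM values are the authors' RSEM transcripts scaled to a common total in each library, deposited per library and in 1 joint table. The joint table was checked against the library files and differed by 0 for all genes with a usable name; 27 names that read as dates were left out of that check. The unstranded STAR counts were used here, and RSEM values entered as alternatives. Gene reads ranged from 8729224 to 23000575 per library, and reads outside the gene counts from 22.6% to 64.0% of all reads. The number of genes at 1 CPM or more had a mean of 10110 in CD11bhi YFP- libraries and 10780 to 11450 in the other groups.

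Library names begin with 1 of 2 prefixes, GS (21 libraries) and BS (12), whose meaning the labels do not give. All spleen and F4/80hi libraries are GS, all CD11bhi libraries BS, and kidney cDC1 and cDC2 hold both, so the prefix term of the model is estimated from the kidney dendritic cells alone, and it moves the folds of CD11bhi against F4/80hi cells. The labels also give 8 sort codes. Whether libraries of 1 sort code are pairs was checked by the correlation of their residuals across genes after the group means were taken out. All 3 pairs were above 0.1 in F4/80hi YFP+ against YFP- (0.112 to 0.426), in kidney against spleen cDC2 (0.103 to 0.128) and in spleen cDC1 against cDC2 (0.126 to 0.299), so a block by sort code was an alternative. The 7 libraries of sort code SR17_017 had more Y-linked transcripts than Xist and the others did not, so each group of GS libraries holds 1 male library in 3, and BS libraries hold none.

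Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and with DESeq2 1.42.0 as an alternative. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 14258 genes, and libraries were scaled by TMM. One quasi-likelihood model with a term per group and a term for the library prefix was fitted to all 33 libraries, so that groups with few libraries borrow the spread of all others. It gave 12 comparisons and 2 interactions, each adjusted by Benjamini-Hochberg over the genes tested. CPM values are TMM-scaled, and where library prefixes differ between groups the fitted fold can differ from the ratio of the CPM means: 3 of the 1720 genes called in CD11bhi YFP+ against F4/80hi YFP+ cells and 1 of the 2839 in the YFP- pair had opposite signs, and 0 elsewhere. Where a group of a comparison had 0 reads, the fold is a bound from 3 counts over that group; for an interaction the fitted difference is given with its SE. With 1 to 3 reads, the ratio of CPM means is given with a 95% exact interval of the count. PCR copies, differences between animals, transcripts lost from a library and the library prefix do not enter these bounds.

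The groups, comparisons, thresholds, 26 gene lists and the rule for named genes were chosen before the data were examined. Named genes were those called, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the 2 groups, without predicted genes, RIKEN clones, microRNA, snoRNA and LOC symbols; the 10 with the largest log2 fold in each direction were taken, with the sort panel and at most 4 called members of each list described. For an interaction, the 5 largest in each direction were taken among called genes with a mean of at least 10 CPM in the highest group. Some genes that the rule takes are not reported here. Levels of uncalled identity genes in the F4/80hi and CD11bhi pairs, and of Xcr1 and Mmp9, were chosen after the values were seen.

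Each list was tested with camera (inter-gene correlation preset to 0.01, and estimated as an alternative) and fry, and called genes were counted over all genes and adjusted over the list alone. The 364 list tests were adjusted together. With voom weights, fry and the estimated correlation also depend slightly on the order of the groups in the model, which was fixed. Camera compares a list with the other genes, while fry, whose values are in the tables alone, tests only whether a list moves one way. Spleen signatures were the 100 genes (alternative 50) highest in 1 of the 3 spleen groups over both others, fitted on the 9 spleen libraries, and were tested in 7 kidney comparisons. Camera, fry and the gene models were tested on simulated data in which 100 genes were changed 2-fold and 100 others 4-fold, in both directions. With edgeR, between 12 and 42 of 100 genes were called at a 2-fold change and between 66 and 93 at a 4-fold change over the 12 comparisons. Between 1 and 6 unchanged genes were called. The changed genes had an average log2 CPM above 2, libraries were drawn independently, and each gene had the same dispersion in all groups. These rates need not hold for scarcer genes, or for groups with a wider spread such as CD11bhi YFP-.

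Alternatives were DESeq2, DESeq2 size factors in edgeR, no filter of low counts, rounded RSEM counts, limma on log2(TPM + 1) and log2(TPM + 0.1), no prefix term, a block by sort code, a model of only the groups compared, fits within 1 prefix, and each library left out in turn. Splits of the samples into groups of the same sizes (at most 100) were tested with limma-trend on log2 CPM of the groups compared, with a prior count of 2 and without the prefix term. Where 100 splits were drawn at random, other draws were seen while the seed was being fixed, and the first draw was kept. Locations are those of GENCODE M21 on GRCm38 (mm10); Cyr61, Ccbl2 and Lphn3 have no entry under these symbols. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw reads were not used here.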

Results

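RNA was sequenced from 33 libraries of 9 sorted cell populations of 10-week-old mice that carry Cre at Clec9a and a YFP reporter at Rosa26, so that cells descended from Clec9a-expressing dendritic cell precursors, and cells that express Clec9a themselves, are YFP+. The kidney gave CD64+ F4/80hi CD11blow and CD64+ F4/80low CD11bhi cells, each split into YFP+ and YFP-, together with YFP+ conventional dendritic cells of type 1 (cDC1) and type 2 (cDC2). The spleen gave YFP- red pulp macrophages (RPM), cDC1 and cDC2. Levels are TMM-scaled CPM of gene reads, given as mean ± SD between libraries, and differences are log2 folds with their SE. A called gene had an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg) and an absolute log2 fold of at least 1, among 14258 genes tested. These p-values rest on a spread estimated over all 33 libraries rather than over the groups compared alone. They can be too small where a group varies more than the others. Libraries that share a sort code entered as independent.

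Transcripts of several sort panel genes followed the gates, while Itgax and Ly6c2 did not in all populations. Emr1 (Adgre1), which encodes F4/80, stood at 2200 ± 328 CPM in F4/80hi YFP- cells (SD, n = 3), 2170 ± 287 in F4/80hi YFP+ (n = 3), 172 ± 36.4 in CD11bhi YFP- (n = 2), 193 ± 55.5 in CD11bhi YFP+ (n = 5), 51.0 ± 13.5 in kidney cDC2 (n = 5) and 2.68 ± 1.20 in kidney cDC1 (n = 6). Fcgr1, which encodes CD64, went from 282 ± 55.4 CPM in F4/80hi YFP- cells to 105 ± 27.9 in CD11bhi YFP+ cells, 15.8 ± 13.1 in cDC2 and 1.54 ± 1.09 in cDC1. Itgam, which encodes CD11b, was at 562 ± 56.4 CPM in CD11bhi YFP+ cells, 608 ± 200 in kidney cDC2, 190 ± 102 in F4/80hi YFP+ and 8.35 ± 3.95 in kidney cDC1. Cd24a reached 616 ± 33.9 CPM in kidney cDC1 against 31.3 ± 5.17 in kidney cDC2. Itgax, which encodes CD11c, was at 166 ± 33.9 CPM in kidney cDC1, which were sorted as CD11c+. It was at 287 ± 29.2 in F4/80hi YFP- cells, whose gate does not name CD11c. Ly6c2 had its highest means in kidney cDC1 (22.6 ± 4.83 CPM) and CD11bhi YFP+ cells (13.2 ± 10.3), although kidney cells were sorted as Ly6C-. The class II gene H2-Ab1 lay between 4030 ± 1730 CPM in RPM and 39400 ± 14600 in kidney cDC2. Clec9a itself was scarce in every population, with the highest means at 2.03 ± 0.302 CPM in spleen cDC1 (n = 3) and 1.31 ± 0.711 in kidney cDC1. Both copies of Clec9a carry Cre in these mice, so these levels need not hold for the unaltered gene. On GRCm38 (mm10), the GENCODE annotation places Adgre1 at chromosome 17: 57358691 to 57483527, Fcgr1 at chromosome 3: 96282909 to 96293969, Itgam at chromosome 7: 128062640 to 128118491, Cd24a at chromosome 10: 43578284 to 43584265, H2-Ab1 at chromosome 17: 34257689 to 34269419 and Clec9a at chromosome 6: 129408862 to 129424763.

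**Figure D1:**
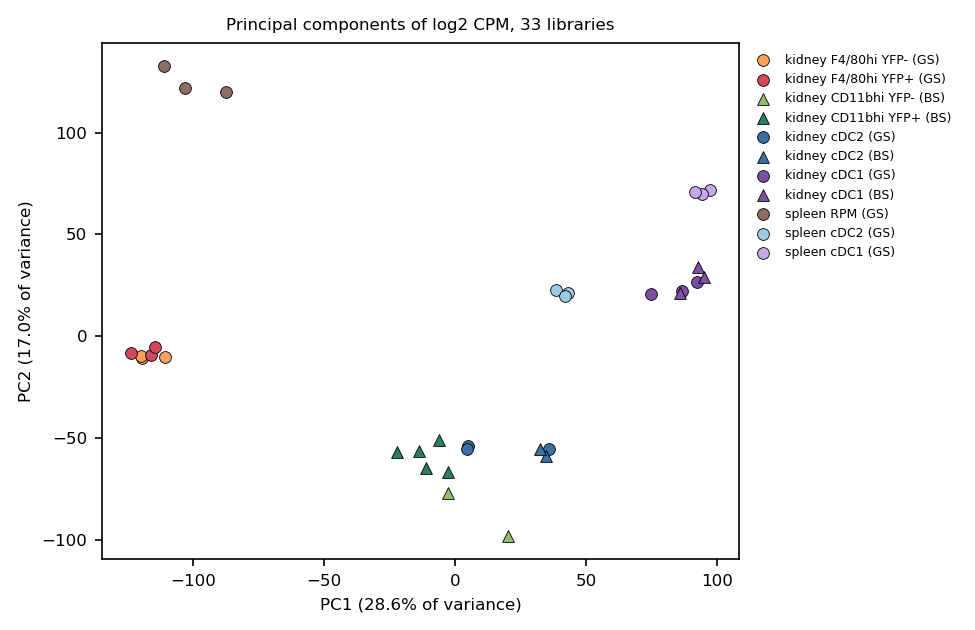
Principal components of log2 CPM in 33 libraries, with 1 point per library, coloured by population and shaped by library prefix. The first component (x axis, 28.6% of variance) and the second (y axis, 17%) place CD11bhi cells near kidney cDC2 and apart from F4/80hi cells.

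Across genes, the mean Pearson correlation of log2 CPM between F4/80hi YFP- and YFP+ libraries was 0.969, against 0.970 and 0.963 within these groups. CD11bhi YFP+ libraries correlated at 0.933 with kidney cDC2 and 0.885 with F4/80hi YFP+. The 2 CD11bhi YFP- libraries correlated with each other at only 0.862. Genes are not independent replicates, so these correlations across genes carry no test.

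In kidney F4/80hi cells, YFP+ and YFP- libraries had similar levels of many macrophage transcripts, and Slc6a12 was the 1 gene called in the model of all libraries. Slc6a12, which encodes the betaine and GABA transporter of osmotically stressed cells, was at 22.1 ± 5.44 CPM in YFP+ cells (SD, n = 3) and 1.38 ± 0.692 in YFP- cells (n = 3), a log2 fold of 3.97 (SE 0.63, adjusted p = 0.0107). It lies at chromosome 6: 121343076 to 121365775. The complement gene C1qa stood at 5740 ± 285 CPM in YFP+ and 5640 ± 101 in YFP- cells, and the collagenase gene Mmp13 at 941 ± 571 and 935 ± 598. The lipoprotein gene Apoe had means of 12600 and 13900 CPM, the growth factor receptor gene Csf1r 4340 and 4180, and Cd81 2850 and 2740, all without a call. Transcripts of the microglia-like list were high in both, with means of 871 and 950 CPM for the fractalkine receptor gene Cx3cr1, 282 and 365 for Tmem119 and 33.2 and 36.5 for Trem2. Of the dendritic cell genes, Zbtb46 was at 1.06 CPM in YFP+ and 1.15 in YFP- cells, and Flt3 at 6.59 and 5.70. The cytokine and chemokine list had a median log2 fold of 0.22 (camera adjusted p = 4.37e-05, and adjusted p = 0.149 with an estimated correlation), and none of its 29 genes was called. The kidney endothelium list had the largest shift, with a median log2 fold of 2.73 (camera adjusted p = 5.22e-17, and 0.000497 with an estimated correlation), 0 of 12 genes called over all genes and 4 adjusted over the list alone. Its members include Egfl7 (log2 fold 4.57, SE 1.40), Ehd3 (4.01, SE 1.25) and the growth factor receptor gene Flt1 (2.87, SE 1.03). Another member, Kdr, was at 6.38 ± 3.43 CPM in YFP+ and 3.48 ± 3.38 in YFP- cells, and lower in YFP+ in replicate 3 (6.15 against 7.29). The list summed to 120 ± 38.3 CPM in YFP+ and 88.1 ± 10.6 in YFP- cells, with ranges that overlapped (79.3 to 155 and 80.5 to 100). The median fold thus overstates the change in its total level.

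With 1 gene called, 132 genes had an unadjusted p under 0.05, DESeq2 called 11 genes and limma on log2(TPM + 1) 8. The 95% interval lay within 2-fold either way for 7787 genes (54.6%), and of 100 genes changed 4-fold in simulated data 85 were called, and of 100 changed 2-fold 25. These simulated genes had an average log2 CPM above 2, so scarcer genes are not covered. The call of Slc6a12 ended without any 1 of the 3 YFP- libraries or without YFP+ replicate 1 (0 genes called each), and when only these 6 libraries were fitted (adjusted p = 0.0561).

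Between kidney CD11bhi YFP+ (n = 5) and YFP- (n = 2) libraries, 619 genes were called higher and 143 lower, and 0 when only these libraries were fitted. Tlr4, which encodes the endotoxin receptor, rose to 73.6 ± 14 CPM (SD, n = 5) from 27.3 ± 6.81 (n = 2), and the lysophospholipid receptor gene Gpr34 to 39.9 ± 4.11 from 16.5 ± 10.2. The transferrin receptor gene Tfrc was at 10.4 ± 3.62 against 0.563 ± 0.796 CPM. Cd200 was at 9.19 ± 3.08 against 0.406 ± 0.575, and the anion transporter gene Slco2b1 at 12.3 ± 4.68 against 1.59 ± 2.25. The interferon-inducible GTPase gene Gbp2b had 22.6 CPM in YFP+ cells and no read in YFP- cells, at least 249-fold. The mitochondrial tRNA synthetase gene Nars2 (log2 fold 5.87, SE 0.61, adjusted p = 9.92e-07), the clock gene Tef (4.72, SE 0.56), Hook2 (4.69, SE 0.56), Spryd4 (4.68, SE 0.72), the cilium gene Bbs9 (4.67, SE 0.52), the valine catabolism gene Aldh6a1 (4.64, SE 0.72), Creld1 (4.46, SE 0.66), Zfp346 (4.45, SE 0.65) and the lymphoid kinase gene Lck (5.11, SE 1.38) rose too. Among genes that fell, the zinc finger gene Zfp329 went to 7.04 ± 1.52 from 33.3 ± 17.6 CPM, the ubiquitin ligase gene Ube2o to 12.9 ± 4.47 from 51.3 ± 29.8, and the porphyrin transporter gene Abcb6 to 6.01 ± 3.21 from 24.6 ± 8.82. Slc35g1, Adcy9, Zscan20, Polq, Ccbl2, Itga1 and Zfp7 fell too, with log2 folds from -3.06 to -1.96.

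Of genes that were not called between the CD11bhi fractions, C1qa was at 620 ± 237 CPM in YFP+ and 411 ± 272 in YFP- cells, and the C-type lectin gene Cd209a at 4140 ± 668 and 3770 ± 121. Mmp13 was at 87.4 ± 46.2 and 68.1 ± 48.7. In the macrophage core list, 7 of 46 genes were called higher and 0 lower, also when adjusted over the list alone (7). These include P2ry13 (at least 31.2-fold, no read in YFP- cells) and Agmo (log2 fold 5.91, SE 1.55); the list's median log2 fold of -0.03 and mean of 0.73 differ in sign (camera adjusted p = 0.866). Over all genes 762 were called, 619 higher and 143 lower. The count fell to 0 when only these 7 libraries were fitted (1700 genes at an unadjusted p under 0.05) and to 0 in the 4 libraries of matched sort codes (191), rose to 2682 without YFP- replicate 2, and was 831 without YFP- replicate 1, with only 300 genes called in the same direction as in the 762. The lists of other cell types all had median log2 folds above 0: B cell 3.75, kidney endothelium 2.79, T and NK cell 1.59, erythroid 1.5, tubule 1.37, fibroblast 1.29, neutrophil 0.69 and plasmacytoid 0.47. Summed over each list, mean CPM in YFP+ and YFP- cells was 61.5 and 55.2 (B cell), 71.9 and 77.1 (endothelium), 73.9 and 33.05 (T and NK cell) and 0.483 and 0.877 (erythroid). It was 951.6 and 938.5 (tubule), 40.4 and 21.6 (fibroblast), 18.7 and 33.4 (neutrophil) and 305 and 304 (plasmacytoid). The medians thus do not show more foreign RNA in YFP+ cells for every list.

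Against F4/80hi YFP+ cells, CD11bhi YFP+ cells carried dendritic cell lectins and transcription factors. Cd209a, an uptake receptor of type 2 dendritic cells, was at 4140 ± 668 CPM in CD11bhi cells (SD, n = 5) and 3.53 ± 3.10 in F4/80hi cells (n = 3), a log2 fold of 10.08 (SE 1.14, adjusted p = 2.54e-07). It lies at chromosome 8: 3743397 to 3748984. The lectin genes of the same cluster rose too: Cd209b reached 42.1 ± 9.52 CPM against 0.09 ± 0.16, while Clec4g (at least 275-fold), Cd209c (at least 312-fold) and Cd209d (at least 187-fold) had no read in F4/80hi cells, as had the resistin-like gene Retnla (at least 961-fold). Zbtb46, a transcription factor gene of conventional dendritic cells, stood at 73.9 ± 7.96 against 1.06 ± 0.557 CPM. Bcl11a was at 49.2 ± 6.72 against 0.888 ± 0.322, and the inhibitory receptor gene Btla at 72.8 ± 15.2 against 0.615 ± 0.669. The calcium-binding gene S100a4 (log2 fold 8.36, SE 0.93), Klrd1 (8.35, SE 0.82), Siglecg (7.92, SE 0.61), Kctd14 (7.85, SE 0.46), the migration gene Ccr7 (2.85, SE 0.93) and the chemokine genes Ccl17 (7.61, SE 0.99) and Ccl22 (4.99, SE 0.69) rose as well.

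Macrophage transcripts fell in the same comparison. Emr1 had a log2 fold of -2.96 (SE 0.34, adjusted p = 2.88e-07) and the selenoprotein transport gene Sepp1 of -2.58 (SE 0.24), from 2020 ± 51.5 to 293 ± 54.4 CPM. The tetraspanin gene Cd81 fell from 2850 ± 662 to 294 ± 72.9 CPM, the scavenger gene Stab1 from 332 ± 69.7 to 11.2 ± 4.72, the complement receptor gene C3ar1 from 907 ± 164 to 68.7 ± 35.9, the TGF-beta receptor gene Tgfbr1 from 1180 ± 310 to 168 ± 83.7, and Apoe from 12600 ± 940 to 226 ± 203. The matricellular gene Cyr61 was at 0.460 ± 0.770 against 202 ± 98.2 CPM and the adhesion gene Vcam1 at 1.95 ± 2.20 against 183 ± 133. Epor, the erythropoietin receptor gene, had no read in CD11bhi cells (at least 831-fold lower). The chemoattractant gene Cxcl1 (log2 fold -7.34, SE 1.82), the red pulp transcription factor gene Spic (-6.95, SE 1.21), the complement gene C2 (-8.62, SE 1.26), Ptprm (-7.14, SE 1.47), Ppp1r9a (-9.29, SE 2.01), B3galnt1 (-8.15, SE 1.73), Cpne8 (-6.94, SE 1.32) and Btbd11 (-6.85, SE 1.24) fell too.

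Gene lists moved with these genes between CD11bhi YFP+ and F4/80hi YFP+ cells. Of 26 pan-cDC genes 17 were called higher and 1 lower (18 and 1 adjusted over the list alone; camera adjusted p = 5.44e-15), and of 46 macrophage core genes 0 higher and 21 lower (23 lower adjusted over the list alone; 1.1e-13). Of 23 cell cycle genes, such as Aurkb at 81.2 ± 6.08 against 9.33 ± 5.04 CPM, 19 were called higher (19 over the list alone; 5.25e-18), and of 20 monocyte genes, such as S100a6 and Plac8, 11 higher (12; 4.19e-08). These 4 lists, the microglia-like list (8 of 15 lower) and the TGF-beta list (4 of 12 lower) kept an adjusted p under 0.05 with an estimated correlation. The dissociation and immediate early list, with Nr4a1 at 1510 ± 576 against 73.7 ± 10.1 CPM and 15 of 23 genes higher (16 over the list alone), had an adjusted p = 1.45e-12 and an adjusted p = 0.154 with an estimated correlation. Over all genes 1720 were called, 1099 higher and 621 lower; the 2 groups also differ in library prefix, and without the prefix term 1870 were called, 916 higher and 954 lower, and on log2(TPM + 1) 601 higher and 1308 lower.

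CD11bhi YFP- cells differed from F4/80hi YFP- cells through many of the same genes. Cd209a stood at 3770 ± 121 CPM (SD, n = 2) against 5.37 ± 3.88 (n = 3), and Zbtb46 at 106 ± 29.1 against 1.15 ± 0.199. Btla was at 64.0 ± 28.7 against 0.703 ± 1.16, and S100a4 at 270 ± 49.0 against 1.06 ± 0.752. The pyrimidine catabolism gene Upb1 (at least 451-fold), Cd209c (at least 493-fold), Galnt9 (at least 182-fold), Clec4g (at least 175-fold) and Cd209d (at least 173-fold) had no read in F4/80hi YFP- cells. Kctd14 (log2 fold 9.81, SE 0.56), the nepmucin gene Cd300lg (7.77, SE 0.94) and the sialic acid receptor gene Siglecg (7.67, SE 0.62) rose too. On the other side, Vcam1 (at least 1810-fold), C2 (at least 273-fold), the growth factor gene Igf1 (at least 414-fold), Gdf3 (at least 130-fold), Meis3 (at least 428-fold), Hs3st1 (at least 542-fold), the phospholipase gene Pla2g7 (at least 2110-fold) and the purinergic receptor gene P2ry13 (at least 468-fold) had no read in CD11bhi YFP- cells. Cyr61 and Btbd11 had 1 read each there, with CPM ratios of 4590 (95% interval 823 to 181000) and 888 (159 to 35100). Such intervals and bounds cover counting error only, and not a loss of scarce transcripts from the 2 CD11bhi YFP- libraries, which is considered below. Pla2g7 and P2ry13 did have reads in CD11bhi YFP+ cells. They were at 25.4 ± 20 and 2.83 CPM there, against 217 ± 92.5 and 43.2 in F4/80hi YFP+ cells. Emr1 fell from 2200 ± 328 to 172 ± 36.4 CPM, Sepp1 from 1960 ± 82.9 to 219 ± 63.5 and Apoe from 13900 ± 2140 to 84.3 ± 52.5.

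In the YFP- fractions, pan-cDC genes were called higher in 16 of 26 and lower in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 5.26e-10, and adjusted p = 0.0755 with an estimated correlation). Macrophage core genes were lower in 21 of 46 (21 over the list alone; 4.81e-09, and adjusted p = 0.0174 with an estimated correlation). Cell cycle genes such as Rrm2 (95.6 ± 38.2 against 15.4 ± 7.54 CPM) were higher in 19 of 23 (21 over the list alone; 1.1e-14, and adjusted p = 0.0836 with an estimated correlation). Over all genes 2839 were called, 1398 higher and 1441 lower, against 1136 and 1703 without the prefix term and 702 and 2396 on log2(TPM + 1). When only these 5 libraries were fitted 1395 were called.

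Kidney F4/80hi YFP+ cells and kidney cDC2 were separated by macrophage against dendritic cell transcripts. Emr1 had a log2 fold of 5.21 (SE 0.29, adjusted p = 6.12e-14) with 2170 ± 287 CPM (SD, n = 3) against 51.0 ± 13.5 (n = 5). The transporter gene Slco2b1 stood at 453 ± 81.0 against 0.05 ± 0.06 CPM, and Mmp13 at 941 ± 571 against 0.0531 ± 0.0561. The chemokine gene Ccl12 was at 202 ± 124 against 0.0991 ± 0.196, and Cyr61 at 202 ± 98.2 against 0.340 ± 0.530. The complement gene C1qb was at 8160 ± 950 against 32.5 ± 39.8 CPM. Csf1r was at 4340 ± 176 against 235 ± 61.1, Axl, a receptor for apoptotic cells, at 1380 ± 38.9 against 138 ± 23.7, and Apoe at 12600 ± 940 against 29.0 ± 49.5. Dlc1 (at least 1880-fold), Mag (at least 514-fold) and Abca14 (at least 343-fold) had no read in cDC2. Ppp1r9a and Epor had 1 read each in cDC2, with CPM ratios of 1020 (95% interval 183 to 40400) and 2800 (503 to 111000). B3galnt1 rose too (log2 fold 10.07, SE 1.31).

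On the cDC2 side, Cd209a was at 3840 ± 334 CPM (SD, n = 5) against 3.53 ± 3.10 in F4/80hi YFP+ cells. Ccl17 was at 144 ± 129 (86.6 ± 9.41 without replicate 3) against 0.303 ± 0.142, Zbtb46 at 134 ± 27.6 against 1.06 ± 0.557, and Ccr7 at 149 ± 63.3 against 2.54 ± 1.33. The class II gene H2-DMb2 was at 532 ± 156 against 9.97 ± 2.30 CPM and the cytokine gene Il1b at 3480 ± 895 against 1050 ± 256. Clec4g (at least 457-fold), Ccdc170 (at least 405-fold), Cd209c (at least 262-fold), the Wnt ligand gene Wnt11 (at least 202-fold), Retnla (at least 220-fold), Sept3 (at least 190-fold), the retinol dehydrogenase gene Dhrs9 (at least 234-fold) and Cd209d (at least 150-fold) had no read in F4/80hi YFP+ cells. Of 46 macrophage core genes 38 were called higher in F4/80hi cells (39 adjusted over the list alone; camera adjusted p = 9.14e-30) and of 26 pan-cDC genes 23 lower (1 higher and 23 lower over the list alone; 5.08e-17), and both kept an adjusted p under 0.05 with an estimated correlation, as did the microglia-like list (11 of 15 higher) and the complement list (12 of 20 higher). Over all genes 2759 were called, 1265 higher and 1494 lower, and on log2(TPM + 1) 1831 higher and 837 lower.

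**Figure D2:**
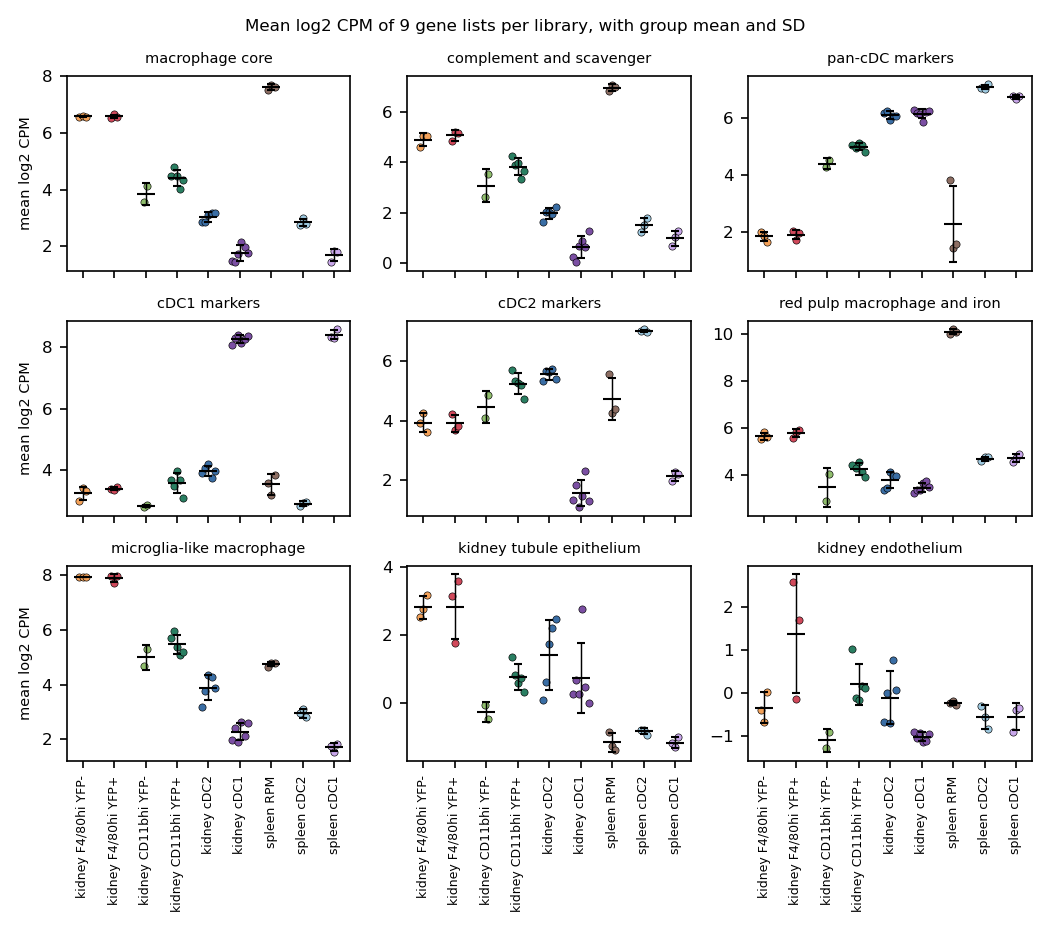
Mean log2 CPM of 9 gene lists (y axis) in 9 populations (x axis), with 1 point per library and bars for the group mean and SD. CD11bhi cells lie between F4/80hi cells and cDC2 in the macrophage core list.

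CD11bhi YFP+ cells and kidney cDC2 differed in 358 called genes, with higher C1qa, C1qb and C1qc in CD11bhi cells. C1qa was at 620 ± 237 CPM in CD11bhi cells (SD, n = 5) and 11.8 ± 16.2 in cDC2 (n = 5), with a log2 fold of 7.81 (SE 0.68, adjusted p = 9.74e-09), and lies at chromosome 4: 136895917 to 136898803. C1qb stood at 1410 ± 406 against 32.5 ± 39.8 CPM, and C1qc at 736 ± 230 against 18.1 ± 27.6. Without cDC2 replicate 3 the cDC2 means of C1qa, C1qb and C1qc were 4.66 ± 3.11, 14.8 ± 5.98 and 5.79 ± 3.07 CPM (n = 4). The elastase gene Mmp12 was at 548 ± 167 against 12.8 ± 11, and Mmp13 at 87.4 ± 46.2 against 0.0531 ± 0.0561. Csf1r was at 1240 ± 261 against 235 ± 61.1 CPM. Cx3cr1 was at 295 ± 112 against 44.4 ± 28.8, and the nuclear receptor gene Pparg at 37.4 ± 12 against 4.56 ± 0.803. Slco2b1 (log2 fold 7.26, SE 1.1), the integrin genes Itga9 (5.82, SE 0.74) and Itga8 (5.61, SE 0.64), C3ar1 (5.21, SE 0.54), Lpl (3.91, SE 0.64), Fcgr1 (4.19, SE 0.58), Emr1 (2.25, SE 0.27) and Axl (2.34, SE 0.21) rose as well.

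Other genes fell in CD11bhi YFP+ cells against cDC2. Kit, a growth factor receptor gene, was at 2.80 ± 2.46 CPM against 55.0 ± 21.4. Ccr7 was at 23.8 ± 12.8 against 149 ± 63.3, and Cd83 at 1260 ± 328 against 4250 ± 787. The lipid scramblase gene Xkrx (log2 fold -4.44, SE 0.98), Adam23 (-3.75, SE 0.47), Sept3 (-3.73, SE 0.58), Mreg (-3.45, SE 0.70), the tight junction gene Cldn1 (-3.18, SE 0.48), Cacnb3 (-3.17, SE 0.83), Ppp1r14a (-3.12, SE 0.56), the immediate early gene Nr4a3 (-3.08, SE 0.52) and Zbtb46 (-1.01, SE 0.24) fell too. Cd209a was not called, at 4140 ± 668 and 3840 ± 334 CPM. Of 46 macrophage core genes 17 were called higher (22 adjusted over the list alone; camera adjusted p = 7.40e-24), of 20 complement genes 11 higher and 1 lower (1.04e-08), of 26 pan-cDC genes 5 lower (11 over the list alone; 3.24e-20), and these lists kept an adjusted p under 0.05 with an estimated correlation. Of 19 maturation genes 4 were called lower (8 over the list alone; 2.96e-11, and adjusted p = 0.0173 with an estimated correlation), and of 23 dissociation and immediate early genes 5 (5; 4.81e-09, and adjusted p = 0.289). Over all genes 358 were called, 209 higher and 149 lower, and 215 within the libraries of prefix BS.

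Of the 1099 genes higher in CD11bhi YFP+ than in F4/80hi YFP+ cells and the 209 higher than in cDC2, 9 were in both, where independent lists would share 16.1. In 20 simulated sets of unchanged groups at most 1 gene was called, so their shared count of 0 is no measure of these 9. Lists of the same sizes from the top of each simulated ranking shared a median of 79 genes and at most 91. Comparisons with a common group thus overlap without any change, so independent lists are not a fair measure. Of these 9, 3 were also called against cDC2 within prefix BS, and 6 had a higher mean CPM than both groups. The chemokine gene Ccl9 was at 505 CPM in CD11bhi YFP+ cells against 206 and 311, and Cd300lb at 47.3 against 9.22 and 11. Within prefix BS, Cd300lb was called against cDC2 and Ccl9 was not. These genes were chosen after their values were seen. Genes lower than in both numbered 15, where independent lists would share 6.49. The 2 comparisons share CD11bhi libraries. With these split into 2 and 3 libraries, 1 part for each comparison, the 20 ways to do so gave 0 to 5 genes higher than both (median 2, independent lists 11.4) and 1 to 8 lower (median 3.5, independent lists 3.10), with fewer libraries in each comparison.

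**Figure D3:**
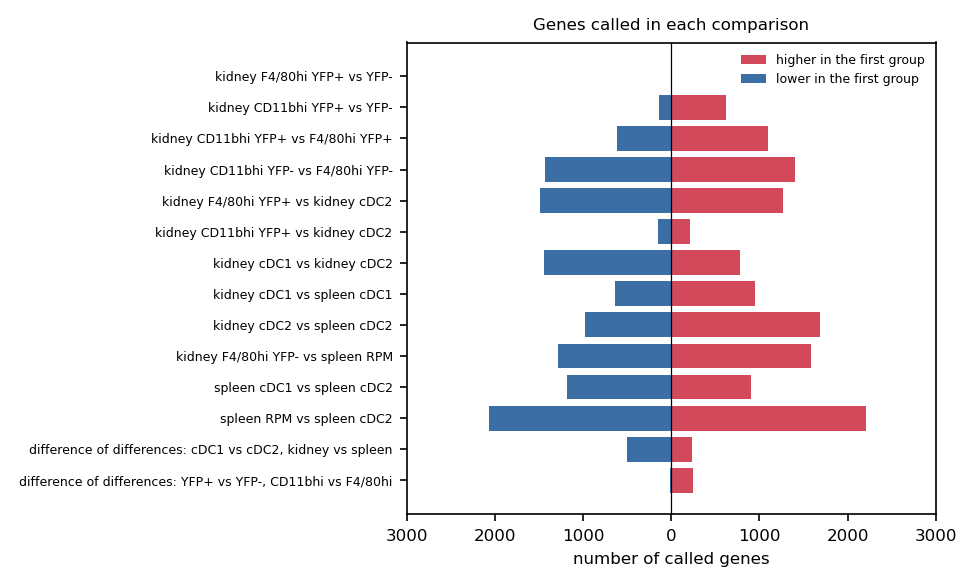
Number of called genes (x axis) in 12 comparisons and 2 interactions (y axis), with bars to the right for genes higher in the first group and to the left for genes lower. F4/80hi YFP+ against YFP- has 1 called gene and RPM against spleen cDC2 has 4278.

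Kidney cDC1 and cDC2 carried the markers of their types. The transcription factor gene Irf8 was at 4630 ± 551 CPM in cDC1 (SD, n = 6) and 42.2 ± 11.4 in cDC2 (n = 5), a log2 fold of 6.79 (SE 0.22, adjusted p = 1.76e-19). The chemokine receptor gene Xcr1 was at 922 ± 169 against 5.12 ± 1.43. The lysosomal thioesterase gene Ppt1 stood at 4730 ± 308 against 233 ± 12.2 CPM, Naaa, which degrades acylethanolamides, at 3280 ± 292 against 261 ± 29.4. Gcsam was at 442 ± 44.6 against 0.154 ± 0.216, and the Wnt receptor gene Fzd1 at 99.1 ± 26.8 against 0.250 ± 0.230. The secreted Wnt regulator gene Dkk3 (at least 1270-fold) and the immunoreceptor adaptor gene Clnk (at least 1110-fold) had no read in cDC2. The sterol hydroxylase gene Cyp8b1 had 1 read in cDC2 and a CPM ratio of 13400 (95% interval 2410 to 529000), Gramd2 1 read and a ratio of 1500 (269 to 59200), and Plce1 2 reads and a ratio of 828 (229 to 6840). Ttc39a (log2 fold 9.86, SE 0.61), the langerin gene Cd207 (7.92, SE 0.73), Itga8 (7.85, SE 0.58) and the DNA synthesis gene Rrm2 (1.37, SE 0.27) rose too.

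In kidney cDC2 against cDC1, the lectin gene Clec10a stood at 905 ± 98.2 CPM (SD, n = 5) against 1.14 ± 0.818 (n = 6), and the signal regulatory gene Sirpa at 430 ± 49.5 against 1.37 ± 0.767. Cd209a was at 3840 ± 334 against 7.80 ± 7.15, the lectin gene Mgl2 at 944 ± 136 against 3.84 ± 2.33, and Sirpb1a at 154 ± 36.4 against 0.250 ± 0.180. Cytokine transcripts went with cDC2: Il1b was at 3480 ± 895 against 117 ± 83.1 CPM. Ccl4 was at 1810 ± 519 against 154 ± 87.3 and Ccl9 at 311 ± 72.0 against 2.85 ± 1.57. The feedback inhibitor gene Socs3 was at 2020 ± 644 against 26 ± 12.1 CPM. The antiviral gene Rtp4 was at 82.2 ± 25 against 2.01 ± 0.896 and the ferritin gene Fth1 at 8740 ± 2500 against 2390 ± 887. In cDC1, Cd209b had 1 read (CPM ratio 2430, 95% interval 435 to 95800), Clec4g 2 (1530, 423 to 12600), Zfp658 2 (1150, 319 to 9510), Abca6 1 (1020, 184 to 40400) and the interleukin-36 receptor gene Il1rl2 1 (1010, 182 to 40000). Of 23 cDC1 marker genes 21 were called higher in cDC1 (21 adjusted over the list alone; camera adjusted p = 1.94e-31), of 17 cDC2 marker genes 1 higher and 14 lower (2 and 14 over the list alone; 5.81e-10), and of 23 dissociation and immediate early genes 19 lower (19 over the list alone; 4.45e-21), all under 0.05 with an estimated correlation. The cytokine list had 1 of 29 genes higher and 16 lower (1.64e-06, and adjusted p = 0.101 with an estimated correlation). Over all genes 2232 were called, 781 higher and 1451 lower, and 1354 within the libraries of prefix BS.

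**Figure D4:**
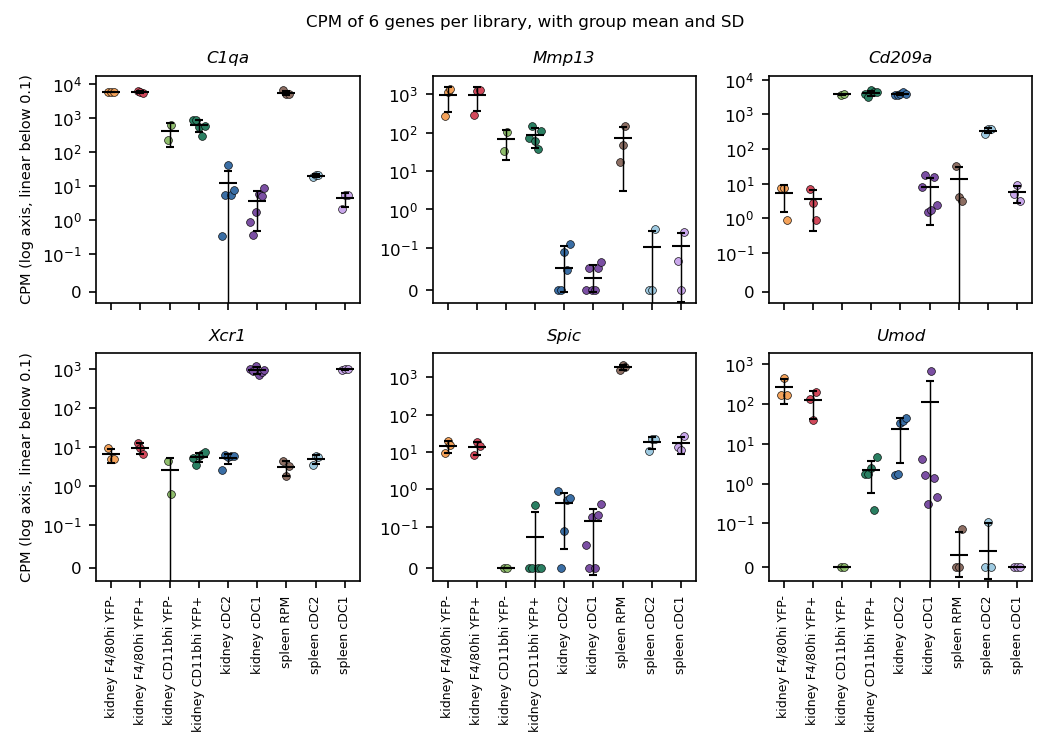
CPM of 6 genes (y axis, log scale, linear below 0.1) in 9 populations (x axis), with 1 point per library and bars for the group mean and SD. Mean Cd209a is 4140 CPM in CD11bhi YFP+ cells and 3840 in kidney cDC2, and mean C1qa 5740 in F4/80hi YFP+ cells.

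Several transcripts of spleen cDC1 were scarce in kidney cDC1. Cd8a, the co-receptor gene of splenic cDC1, was at 25.4 ± 7.71 CPM in kidney (SD, n = 6) and 942 ± 67.0 in spleen (n = 3), a log2 fold of -5.60 (SE 0.63, adjusted p = 2.52e-07). The glycoprotein gene Gp2 had 1 read in kidney cDC1 against 156 ± 91.7 CPM in spleen, a ratio of 14900 (95% interval 2680 to 590000). The protease inhibitor gene Serpinb2 was at 1.25 ± 0.810 against 57.9 ± 11.3 CPM, and the immediate early gene Egr3 at 8.15 ± 2.36 against 224 ± 65.6. The maturation gene Cd83 was at 543 ± 181 against 2820 ± 122, and Il1b at 117 ± 83.1 against 1010 ± 68.0. Lphn3 (log2 fold -7.90, SE 0.83), the proprotein convertase gene Pcsk5 (-7.87, SE 2.14), Spic (-6.60, SE 0.68), Cd300e (-5.35, SE 0.59), Efcc1 (-5.18, SE 1.04) and the short-chain fatty acid receptor gene Ffar2 (-4.90, SE 0.82) fell too. Xcr1 was not called, at 922 ± 169 and 970 ± 26.9 CPM.

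In the other direction, the chemokine receptor gene Ccr2 stood at 993 ± 289 CPM in kidney cDC1 against 29.9 ± 9.35 in spleen, and Siglech at 24.2 ± 7.49 against 0.446 ± 0.463. The leukotriene receptor gene Ltb4r1 was at 24.3 ± 14.2 against 0.270 ± 0.130, Cd300lg at 16.9 ± 5.82 against 0.180 ± 0.150, and Xaf1, an interferon-induced gene, at 45.9 ± 10.6 against 7.76 ± 2.61. Mmp14, which encodes a membrane protease, had 2 reads in spleen cDC1 and a CPM ratio of 568 (157 to 4690). Tubule transcripts led the genes that rose: Umod (at least 1680-fold), Klk1 (at least 555-fold), Wfdc15b (at least 348-fold) and Kng2 (at least 161-fold) had no read in spleen cDC1, and Fxyd2 (log2 fold 7.08, SE 0.91), Ldhb (7.01, SE 1.13) and Atp1b1 (6.77, SE 1.53) rose. Kidney cDC1 replicate 4 carried most of them, with Umod at 665 CPM against 0.299 to 4.27 in the other libraries of its group. Of 17 tubule genes 9 were called higher (11 adjusted over the list alone; camera adjusted p = 0.00817, and adjusted p = 0.464 with an estimated correlation). The maturation list had 8 of 19 genes lower and 1 higher (9 and 2 over the list alone; 1.97e-07, and adjusted p = 0.0836 with an estimated correlation). Over all genes 1584 were called, 949 higher and 635 lower, and 339 higher and 1339 lower on log2(TPM + 1). Without kidney cDC1 replicate 4 the count was 998, 521 higher and 477 lower.

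Kidney and spleen cDC2 differed by several receptor and chemokine genes. The Notch regulator gene Dtx1 was at 0.142 ± 0.271 CPM in kidney (SD, n = 5) and 376 ± 114 in spleen (n = 3), a log2 fold of -12.29 (SE 1.19, adjusted p = 4.40e-09). Clec4a4, an inhibitory lectin gene of splenic cDC2, stood at 1.41 ± 1.22 against 169 ± 13.2 CPM. Cd4 was at 5.46 ± 2.89 against 292 ± 33.4 and the calcium channel gene Ryr3 at 0.290 ± 0.190 against 163 ± 65.1. The succinate receptor gene Sucnr1 (at least 758-fold), the cadherin gene Cdh17 (at least 791-fold) and the sodium channel gene Scn3a (at least 1390-fold) had no read in kidney cDC2. Dnajc22, Cdcp1 and Bmp8a had 1 read each, with CPM ratios of 991 (95% interval 178 to 39200), 1910 (343 to 75400) and 1370 (246 to 54000). Dpp10 (log2 fold -9.09, SE 1.44) and Tmem132c (-8.64, SE 1.62) fell too, as did the B cell antigen gene Ms4a1 (-4.97, SE 0.80).

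Higher in kidney cDC2 were Ccl17 (144 ± 129 against 0.197 ± 0.215 CPM, and 86.6 ± 9.41 without kidney replicate 3), Ccl6 (608 ± 85.4 against 42.1 ± 0.392), Ccl2 (104 ± 35.1 against 2.48 ± 0.636), Ccr2 (631 ± 178 against 24.3 ± 6.23), the haemoglobin scavenger receptor gene Cd163 (121 ± 66.1 against 2.03 ± 1.95) and Cd209a (3840 ± 334 against 340 ± 59.7). The heat shock gene Hspa1a was at 3060 ± 442 against 359 ± 161 CPM and Socs3 at 2020 ± 644 against 35.2 ± 3.78. The Fc receptor-like gene Fcrls had 2 reads in spleen cDC2 and a CPM ratio of 1250 (346 to 10300). Retnla (at least 232-fold), Angptl2 (at least 156-fold) and the basement membrane gene Col4a2 (at least 275-fold) had no read in spleen cDC2, nor had the kidney epithelial genes Defb1 (at least 412-fold), Kng2 (at least 203-fold) and Sfrp1 (at least 196-fold). Klk1 and Calb1 had 1 read each there, with ratios of 2650 (476 to 105000) and 1910 (342 to 75300).

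Between kidney and spleen cDC2, 14 of 23 dissociation and immediate early genes, Socs3 and Hspa1a among them, were called higher and 2 lower (15 and 2 adjusted over the list alone; camera adjusted p = 1.61e-08, and adjusted p = 0.317 with an estimated correlation), 14 of 29 cytokine genes higher and 3 lower (14 and 3; 0.00364, and adjusted p = 0.352), and 11 of 17 tubule genes higher (11; 0.00616, and adjusted p = 0.430). Over all genes 2675 were called, 1691 higher and 984 lower. On log2(TPM + 1) 558 were higher and 3403 lower, and on log2(TPM + 0.1) 4651 were called, 770 higher and 3881 lower.

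Kidney F4/80hi YFP- cells and RPM expressed different macrophage programmes. The iron-handling genes went with RPM: Hmox1, which degrades haem, was at 146 ± 24.9 CPM in F4/80hi cells (SD, n = 3) and 10200 ± 1490 in RPM (n = 3), a log2 fold of -6.13 (SE 0.43, adjusted p = 5.79e-12). Spic stood at 14.8 ± 5.15 against 1850 ± 261 CPM, the integrin gene Itgad at 0.178 ± 0.0394 against 1420 ± 296, Treml4 at 19.4 ± 5.31 against 1620 ± 266, and the ficolin gene Fcna at 0.530 ± 0.230 against 6638 ± 1923. The scavenger protein gene Cd5l was at 0.203 ± 0.178 against 2240 ± 677, Slpi at 0.310 ± 0.200 against 3060 ± 150, and Cd163 at 0.762 ± 0.735 against 454 ± 140. The monocarboxylate transporter gene Slc16a9 (at least 4870-fold) and Dgki (at least 829-fold) had no read in F4/80hi YFP- cells. Pla2g2d, Ubd and Pcolce2 had 1 read each and Gfra2 2, with CPM ratios of 11500 (95% interval 2070 to 455000), 8020 (1440 to 317000), 6220 (1120 to 246000) and 9690 (2680 to 80000). The erythroid gene Alas2 and the B cell adaptor gene Bank1 were also lower in F4/80hi cells (log2 folds -8.24, SE 1.56, and -4.64, SE 0.55).

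Higher in F4/80hi YFP- cells than in RPM were Cx3cr1 (950 ± 30.0 against 14.8 ± 11.2 CPM), Tmem119 (365 ± 47.5 against 7.50 ± 3.31), Cd72 (1350 ± 155 against 15.0 ± 12.1), H2-Ab1 (31000 ± 3580 against 4030 ± 1730), Itgam (223 ± 139 against 12.5 ± 3.65), Tgfbr1 (1230 ± 145 against 108 ± 53.6) and the chemokine gene Cxcl16 (1320 ± 181 against 43.7 ± 32.7). The oxysterol gene Ch25h and the transcription factor gene Creb5 had 1 read each in RPM, with CPM ratios of 9290 (1670 to 367000) and 5420 (972 to 214000), and the alarmin receptor gene Il1rl1 none (at least 635-fold). Tubule transcripts rose as well: Calb1 (at least 1510-fold), Defb1 (at least 964-fold), Wfdc15b (at least 780-fold), Cdh16 (at least 661-fold), Sostdc1 (at least 493-fold) and Cxcl14 (at least 435-fold) had no read in RPM, and Umod 1, against 263 ± 164 CPM in F4/80hi YFP- cells. Of 20 red pulp and iron genes 17 were called lower (17 adjusted over the list alone; camera adjusted p = 3.30e-23) and of 15 microglia-like genes 9 higher and 1 lower (10 and 1 over the list alone; 4.37e-05), both under 0.05 with an estimated correlation, while 9 of 17 tubule genes were higher (10 over the list alone; 0.00530, and adjusted p = 0.430). Over all genes 2867 were called, 1581 higher and 1286 lower.

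In the spleen, cDC1 and cDC2 separated by the same marker lists as in the kidney. Irf8 was at 4140 ± 282 CPM in cDC1 (SD, n = 3) and 50.5 ± 4.12 in cDC2 (n = 3), a log2 fold of 6.36 (SE 0.28, adjusted p = 2.53e-16). Ppt1 was at 6900 ± 496 against 182 ± 6.61, the adhesion gene Cadm1 at 833 ± 139 against 10.2 ± 2.72 and Naaa at 2660 ± 155 against 41.3 ± 2.63. Fzd1 (at least 1690-fold), Mab21l3 (at least 823-fold), Gramd2 (at least 509-fold), Ctla2b (at least 408-fold), Homer2 (at least 326-fold), Igf2r (at least 260-fold), Pcsk5 (at least 260-fold) and the collagen-binding integrin gene Itga1 (at least 244-fold) had no read in cDC2, while Gcsam and Dkk3 had 1 each (CPM ratios 18400, 3310 to 728000, and 5970, 1070 to 236000). In cDC2, Sirpa was at 1020 ± 65.8 against 3.13 ± 1.64 CPM, and S100a4 at 339 ± 59.0 against 2.04 ± 0.869. Rtp4 was at 82.2 ± 23.3 against 0.582 ± 0.277 and the viral RNA sensor gene Ddx58 at 94.8 ± 7.56 against 1.43 ± 0.978. The gelatinase gene Mmp9 (at least 1530-fold), Sucnr1 (at least 387-fold), the flagellin receptor gene Tlr5 (at least 376-fold), Cd300lb (at least 271-fold), Tmem132c (at least 249-fold) and Scel (at least 241-fold) had no read in cDC1. Clec4a4 had 3 reads (ratio 2520, 864 to 12200) and Myo1e 1 (2350, 421 to 92700), and Sirpb1a (log2 fold -10.06, SE 0.58) and Dscam (-9.28, SE 1.65) were lower in cDC1.

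Of 23 cDC1 marker genes 21 were called higher in spleen cDC1 (21 adjusted over the list alone; camera adjusted p = 5.38e-37), and of 17 cDC2 marker genes 1 higher and 16 lower (1 and 16; 8.50e-14), both under 0.05 with an estimated correlation. The interferon-stimulated list had 1 of 21 genes higher and 12 lower (1 and 13; 3.13e-05, and adjusted p = 0.472 with an estimated correlation). Over all genes 2084 were called, 901 higher and 1183 lower, and 663 higher and 1507 lower on log2(TPM + 1). In the kidney cDC1 against cDC2 comparison, the 100 genes most specific to spleen cDC1 had a median log2 fold of 3.92 with 77 called higher (camera adjusted p = 2.58e-49), and the 100 genes of spleen cDC2 a median of -2.43 with 48 lower and 2 higher (8.55e-12), both under 0.05 with an estimated correlation. With 50 genes the spleen cDC2 signature had an adjusted p = 0.144 with an estimated correlation. The 100 RPM genes had a median of 1.80 in CD11bhi YFP+ cells against cDC2, with 13 higher (5.11e-08, and adjusted p = 0.0766 with an estimated correlation).

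Of the 12 comparisons, RPM against spleen cDC2 had the most called genes. Axl was at 3400 ± 501 CPM in RPM (SD, n = 3) and 16.4 ± 3.38 in cDC2 (n = 3), a log2 fold of 7.69 (SE 0.30, adjusted p = 2.07e-17), and C1qb at 7830 ± 1770 against 25.8 ± 1.12. Csf1r was at 7340 ± 998 against 340 ± 24.6, Cd14 at 1350 ± 197 against 13.3 ± 2.76, Cd5l at 2240 ± 677 against 2.58 ± 1.45 and the mannose receptor gene Mrc1 at 1300 ± 474 against 2.41 ± 1.48. The growth factor genes Pdgfc (at least 839-fold) and Kitl (at least 479-fold), Sema6a (at least 420-fold), Rgl3 (at least 416-fold), Mag (at least 387-fold), Snx31 (at least 339-fold), Mybpc1 (at least 304-fold), Nfasc (at least 301-fold) and Ucp3 (at least 263-fold) had no read in cDC2, and the collagen gene Col14a1 had 1 (CPM ratio 4040, 95% interval 726 to 160000). In cDC2, the kinase gene Lrrk2 was at 266 ± 23.5 against 3.20 ± 3.06 CPM. Irf4 was at 152 ± 46.6 against 8.59 ± 5.17, H2-Ab1 at 17400 ± 662 against 4030 ± 1730 and Itgax at 850 ± 32 against 130 ± 7.93. Dscam (log2 fold -6.56, SE 1.41), Rundc3b (-6.28, SE 1.62), Scn3a (-6.28, SE 1.38), Cdcp1 (-6.21, SE 1.26), Nr4a3 (-6.16, SE 0.72), Scel (-6.11, SE 0.97), Mfsd6 (-6.06, SE 0.65) and Bmp8a (-5.99, SE 1.36) were lower in RPM, and Myo1h had 3 reads there (ratio 254, 86.8 to 1230).

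Of 26 pan-cDC genes 26 were called lower in RPM than in spleen cDC2 (26 adjusted over the list alone; camera adjusted p = 1.63e-19), of 46 macrophage core genes 42 higher (44 over the list alone; 1.94e-31) and of 20 red pulp and iron genes 19 higher and 1 lower (19 and 1; 8.23e-20), all under 0.05 with an estimated correlation. Of 23 cell cycle genes 22 were lower (22; 8.96e-12, and adjusted p = 0.132 with an estimated correlation). Over all genes 4278 were called, 2207 higher and 2071 lower, and 1539 higher and 2803 lower on log2(TPM + 1).

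The cDC1 to cDC2 difference itself differed between kidney and spleen for 747 genes, 238 with a higher and 509 with a lower log2 fold in the kidney (753 higher and 406 lower on log2(TPM + 1)). Mmp9 was at 102 ± 29.6 CPM in spleen cDC2 (SD, n = 3) and at most 0.557 ± 1.25 in the other 3 groups. Tlr5 was at 25.1 ± 3.57 in spleen cDC2 and at most 0.253 ± 0.619 elsewhere, and Dtx1 at 376 ± 114 and at most 0.867 ± 0.279. Mmp14 was lower in spleen cDC1 than in spleen cDC2 (0.0440 ± 0.0381 and 16.3 ± 3.67 CPM) and higher in kidney cDC1 than in kidney cDC2 (25.3 ± 9.06 and 7.79 ± 7.51). Flt1, a growth factor receptor gene, was at 24.2 ± 4.11 CPM in spleen cDC1 and at most 2.46 ± 0.920 elsewhere. Il1rl2 was at 10.6 ± 6.96 in kidney cDC2 and at most 0.102 ± 0.177 elsewhere. Of 29 cytokine genes 12 had a lower log2 fold in the kidney (1 higher and 16 lower adjusted over the list alone; camera adjusted p = 1.44e-08) and of 23 cDC1 marker genes 9 (1 and 9; 2.85e-05), both under 0.05 with an estimated correlation. Of 23 dissociation and immediate early genes 15 had a lower one (16 over the list alone; 5.87e-21, and adjusted p = 0.0498 with an estimated correlation).

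The YFP+ to YFP- difference differed between CD11bhi and F4/80hi cells for 262 genes, 245 with a higher and 17 with a lower log2 fold in CD11bhi cells. Pla2g7, which degrades platelet-activating factor, was at 25.4 ± 20 CPM in CD11bhi YFP+ cells (SD, n = 5) without a read in CD11bhi YFP- cells (n = 2), and at 217 ± 92.5 and 191 ± 98.3 in the F4/80hi pair. The death ligand gene Tnfsf10, the ornithine carrier gene Slc25a15 and the keratin gene Krt7 also had no read in CD11bhi YFP- cells and were not called in F4/80hi cells. Slc6a12 (log2 fold difference -3.65, SE 0.80), Polq (-3.15, SE 0.81), Zfp329 (-2.37, SE 0.45), Ube2o (-2.01, SE 0.50) and Rpusd1 (-1.80, SE 0.44) went the other way. Without CD11bhi YFP- replicate 2 the count was 1978, without F4/80hi YFP+ replicate 2 it was 156, and with only these 4 groups fitted it was 27.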

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

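The tests of endothelial transcripts, of the CD11bhi count, of a mixture and of the library prefix were chosen only after the results were seen. The splits of the samples were written before their own results were seen, but after the counts of called genes.

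The endothelium list had a higher mean log2 CPM in F4/80hi YFP+ than in YFP- cells, with library means of 2.59, -0.128 and 1.70 in YFP+ and -0.387, -0.671 and 0.036 in YFP- replicates 1 to 3, which share sort codes. In summed CPM the ranges overlapped, with 79.3 to 155 in YFP+ and 80.5 to 100 in YFP- libraries. RNA or cells of the kidney endothelium in single libraries could give the higher log2 means and cannot be told apart: by these means YFP+ lay above YFP- in 3 of 3 pairs, but by 0.543 in the smallest, against an SD of 0.356 between YFP- libraries. A link of these transcripts to the reporter cannot be told apart either: the list had a median log2 fold of 2.79 between the CD11bhi fractions, where the 7 lists of other foreign cells also lay above 0, from 0.47 (plasmacytoid) to 3.75 (B cell). In summed CPM the endothelium list was at 71.9 ± 7.72 in CD11bhi YFP+ and 77.1 ± 0.787 in CD11bhi YFP- cells, so the median does not measure its total level.

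The 762 genes called between CD11bhi YFP+ and YFP- cells may reflect scarce transcripts lost from the 2 YFP- libraries. By their level in YFP+ cells, 6.30% of 4790 genes at 5 CPM or less (302 genes) and 5.16% of 5877 at 5 to 50 CPM (303) were called higher. At 50 CPM or more it was 0.390% of 3591, a ratio of 16.2 between the lowest and highest class. Genes called lower numbered 26, 114 and 3 in these classes and also thinned out at the highest level, so the ratio is not specific to such a loss. Low complexity of YFP- replicate 1 alone cannot be told apart: without it 300 of the 762 (39.4%) were called again in the same direction, with 1 YFP- library left. Spread borrowed from quieter groups could also give the calls. The coefficient of biological variation was 0.995 in the 2 YFP- libraries and 0.543 in the 7 CD11bhi libraries against 0.393 over all 33, ratios of 2.53 and 1.38, and 0 genes were called when only the CD11bhi libraries were fitted.

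CD11bhi YFP+ cells lay between F4/80hi cells and cDC2 in the macrophage core list. A library prefix effect of the size seen in kidney dendritic cells does not account for the difference from F4/80hi cells. The list mean of log2 CPM differed from that of F4/80hi cells by -2.16 without the prefix term and by -1.81 (SE 0.17) with it. Between prefixes the list mean differed by at most 0.41 within kidney cDC1 and cDC2, which alone set the term. A larger prefix effect in the other cells cannot be excluded, since all F4/80hi libraries are GS and all CD11bhi libraries BS. In single genes the prefix cannot be told apart: of 31 macrophage core genes called lower than in F4/80hi cells without the term 21 stayed so with it, and the other 10 went from a median log2 fold of -2.31 (median SE 0.51) to -0.84 (0.59), so their calls ended mostly through smaller folds. Among these, Mertk went from -4.63 to 0.03 and Tlr7 from -3.82 to 0.61, while Fgd4 went from -1.83 to -2.01. Mean CPM in CD11bhi YFP+ and F4/80hi YFP+ cells was 0.822 and 20.9 for Mertk, and 8.76 and 125 for Tlr7. In kidney cDC2, which help set the term, they were scarce (0.184 and 0.397 CPM). For such genes the term is poorly known, and an ended call does not show a prefix effect. A single share for all macrophage genes cannot be told apart, since the term decides it: 24 of 38 macrophage core genes lay more than 2 SE from the median position of 13.3% in CPM, but 12 of 38 from a median of 18.1% in folds with the term. A mixture of F4/80hi-like cells and cDC2 in the gate, with shares or levels that differ between genes, cannot be told apart. The labels give the gate as CD64+ F4/80low CD11bhi, and cDC2 as CD64-. Of 9 genes called higher than in both and 15 called lower, 6 and 15, 21 in all, also had a mean CPM outside both, which no mixture of the 2 gives. The threshold allows 17.9 false calls among all 358 genes called against cDC2, and how many fall among these 21 is not known. Of the 6 genes 3, and of the 15 genes 11, stayed under 10 CPM in all 3 groups.

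Splits of the samples into other groups of the same sizes were tested with a simpler model, without the library prefix. They treat libraries as exchangeable and ignore sort codes. In the following comparisons only 1 split, the real one, called as many genes as the real split. These were CD11bhi YFP+ against F4/80hi YFP+ (2091 genes, highest other split 0, 56 splits), F4/80hi YFP+ against cDC2 (2615 and 124, 56 splits) and CD11bhi YFP+ against cDC2 (452 and 23, 100 splits). The others were kidney cDC1 against cDC2 (1988 and 1216, 100 splits), and kidney against spleen cDC1 (1144 and 0, 84 splits) and cDC2 (2156 and 1, 56 splits). Other splits mix cells sorted as different populations, so this outcome was likely from the start. It does not part cell type from library prefix, sort code or other differences between the groups. For the difference of cDC1 and cDC2 between kidney and spleen, 2 of 100 splits, the real one among them, called as many as the real 1031, with a highest of 1819. For F4/80hi YFP+ against YFP-, F4/80hi YFP- against RPM, spleen cDC1 against cDC2 and RPM against spleen cDC2 the 10 splits are too few. Of them 10, 1, 1 and 1 called as many genes as the real split. In F4/80hi YFP+ against YFP- the real split called 0 genes in this model, so all 10 splits had to call as many.

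A library stood apart from the rest of its group in 13 of 27 library measures, 5 of 72 list means, 6 of 30 sort panel genes and 14 of 94 named genes, where chance would do so in about 1 in 20 groups. Only CD11bhi YFP+ cells, kidney cDC1 and kidney cDC2 were screened. The limit to named genes with a mean of at least 10 CPM was chosen after the data were seen, and without it 52 of 192 stood apart.

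Kidney cDC1 replicate 4 had 16.4% multimapping reads (other libraries 13.9% to 14.8%), 7.35% outside genes (11.6% to 13.7%), 1.31% ambiguous (0.970% to 1.09%), 44.3% in its top 100 genes (31.3% to 34.8%) and a mean transcript length of 2030 bp (2510 to 2770). Its levels were 5.01 CPM for Emr1 (1.80 to 2.79), 55400 for H2-Ab1 (21400 to 27400), 665 for Umod (0.299 to 4.27), 136 for Wfdc15b (0.359 to 1.28), 55.9 for Kng2 (0.179 to 3.67), 114 for Fxyd2 (4.90 to 20.8), 75 for Ldhb (2.33 to 4.61) and 59.5 for Atp1b1 (1.08 to 7.51), with list means of log2 CPM of 2.77 for tubule genes (0.013 to 0.684) and 5.86 for pan-cDC genes (6.14 to 6.28). Kidney cDC1 replicate 6 had 8.44% unmapped reads (2.73% to 3%) and a strand ratio of 0.955 (others 1.01), and all 7 libraries of sort code SR17_022, among them kidney cDC2 replicate 5, had 7.08% to 8.44% and 0.955 to 0.968.

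Kidney cDC2 replicate 3 had 14.4% multimapping reads (12.2% to 12.7%), 369 CPM of Ptprc (896 to 1070), 64800 of H2-Ab1 (27600 to 36300), 376 of Ccl17 (74.9 to 96.3), 40.4 of C1qa (0.334 to 7.73), 103 of C1qb (6.49 to 20.4), 67.1 of C1qc (1.81 to 9.14) and 57.7 of Ppp1r14a (18.7 to 25.9), and a cell cycle list mean of 6.03 (5.48 to 5.63). Replicate 5 of the same group had 7.34% unmapped reads (2.35% to 2.79%), a strand ratio of 0.958 (1 to 1.01) and 13.9 CPM of Angptl2 (8.63 to 9.99), and replicate 1 a plasmacytoid list mean of 2.16 (2.90 to 3.19). CD11bhi YFP+ replicate 4 had 45.8% unmapped reads (2.35% to 2.80%), 7.42% multimapping (12.3% to 12.8%), 0.615% ambiguous (1.16% to 1.29%) and 55.8 CPM of Fcgr1 (113 to 127). In the same group, replicate 1 had 0.656 CPM of Clec9a (0 to 0.0631) and an endothelium list mean of 1.02 (-0.158 to 0.175), replicate 5 had 11.2 CPM of Aldh6a1 (19.6 to 21.6), and replicate 2 had 93.8 of Itga9 (33.2 to 39.5).

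The difference of cDC1 and cDC2 itself differed between kidney and spleen for 747 genes, with fitted log2 differences of 10.20 for Mmp14 (SE 1.07), 10.19 for Dtx1 (SE 1.59), -8.80 for Flt1 (SE 1.26) and -8.30 for Il1rl2 (SE 2.31). Where a group had no read, the size is set by the model: 15.76 for Sucnr1 (SE 3.47), 11.82 for Mmp9 (SE 3.50), 11.27 for Tlr5 (SE 3.27), -11.56 for Pcsk5 (SE 3.12), -9.86 for Sfrp1 (SE 2.96) and -8.83 for Itga1 (SE 1.44). The difference of YFP+ and YFP- cells differed between CD11bhi and F4/80hi cells for 262 genes, with -3.65 for Slc6a12, -3.15 for Polq, -2.37 for Zfp329, -2.01 for Ube2o and -1.80 for Rpusd1, and, without a read in CD11bhi YFP- cells, 11.44 for Pla2g7 (SE 2.81), 9.50 for Krt7 (SE 1.59), 9.44 for Tnfsf10 (SE 2.37) and 9.40 for Slc25a15 (SE 1.45).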

How the results depend on the processing

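Of 134 other settings tried for the counts of called genes, 118 stayed within 1.5 times and 16 did not, and the cause was not tested unless said. This rule compares totals alone, and the balance of directions could turn among the 118. On log2(TPM + 1) the balance of called genes moved from mostly higher to mostly lower in kidney against spleen cDC1 and cDC2. The same held for CD11bhi against F4/80hi YFP+ and RPM against spleen cDC2. In F4/80hi YFP+ against cDC2 the balance moved from mostly lower to mostly higher. This is a change in which genes were called, and not a change of sign in single genes. TPM values were not scaled by TMM. For F4/80hi YFP+ against YFP- (1 gene), DESeq2 called 11, log2(TPM + 1) 8, no filter 2, RSEM counts 2 and the fit of only the groups compared 0. For CD11bhi YFP+ against YFP- (762), DESeq2 called 1287, and both the fit of only the groups compared and the 4 libraries of matched sort codes 0. Fewer libraries leave fewer degrees of freedom. The spread was also wider, with a coefficient of biological variation of 0.543 in the 7 CD11bhi libraries against 0.393 over all 33. These 2 were not told apart. For CD11bhi YFP- against F4/80hi YFP- (2839), the fit of only the groups compared called 1395. Within prefix BS, with fewer libraries, CD11bhi YFP+ against cDC2 (358) gave 215 and kidney cDC1 against cDC2 (2232) 1354. Kidney against spleen cDC2 (2675) gave 4651 on log2(TPM + 0.1). The organ difference of cDC1 and cDC2 (747) gave 1159 on log2(TPM + 1), and the YFP difference of CD11bhi and F4/80hi cells (262) gave 535 with DESeq2, 105 on log2(TPM + 1) and 27 with only the groups compared. Of 364 list tests, 113 had an adjusted p under 0.05 with the preset and 37 with the estimated correlation.

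Leaving out 1 library at a time gave 0 to 2 genes for F4/80hi YFP+ against YFP-, 646 to 2682 for CD11bhi YFP+ against YFP-, 1276 to 1861 for CD11bhi against F4/80hi YFP+, 2344 to 4066 for the same in YFP- cells, 2293 to 2898 for F4/80hi YFP+ against cDC2, 249 to 386 for CD11bhi YFP+ against cDC2, 2016 to 2360 for kidney cDC1 against cDC2, 998 to 1905 for kidney against spleen cDC1 and 2161 to 2843 for cDC2. It gave 2363 to 2679 for F4/80hi YFP- against RPM, 1748 to 1832 for spleen cDC1 against cDC2, 3833 to 4122 for RPM against spleen cDC2, 606 to 817 for the organ difference and 156 to 1978 for the YFP difference. Without a CD11bhi YFP- library, the lone one left is assumed to vary like the other groups.

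Alternatives chosen after the data were seen left out sort code SR17_017. Without all its libraries 0 genes were called between F4/80hi YFP+ and YFP-. Without its kidney dendritic cells, 966 genes were called between kidney and spleen cDC1, and without all its libraries 831, with 1658 between kidney and spleen cDC2 and 109 for the YFP difference. Of 1011 pairs of a named gene and a comparison, DESeq2 kept 988 called, RSEM counts 1001, no prefix term 979 and the sort code block 962. The fit of only the groups compared kept 889 of 989, log2(TPM + 1) 894 of 1009 and log2(TPM + 0.1) 927 of 1009, and 0 turned direction in these 7 settings or in the 2 others tried. Named genes were taken because they were called in these data, many without overlap between libraries. Few of them could turn, so these shares say little about other genes. A gene at 1 CPM had 7.78 reads in the shallowest library and 20.9 in the deepest, which limits what can be called at low levels.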

Other observations

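The noncoding gene at the reporter's locus, Gt(ROSA)26Sor (chromosome 6: 113067428 to 113077333), was at 1.81 ± 0.515 CPM in F4/80hi YFP+ cells (SD, n = 3) and 0.660 ± 0.331 in YFP- cells (n = 3), and at 2.20 ± 0.744 in CD11bhi YFP+ (n = 5) and 0.421 ± 0.0653 in YFP- cells (n = 2). It was called in CD11bhi cells (adjusted p = 0.0268) and not in F4/80hi cells, and was chosen after its values were seen. A call in 1 pair alone does not show that the pairs differ. The gene is scarce, and no gene was called when only the CD11bhi libraries were fitted.

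Transcripts of other cells were present in several populations. The 4 erythroid genes summed to 59.6 ± 45.9 CPM in RPM (SD, n = 3) and at most 2.96 ± 3.83 elsewhere, and the B cell genes to 640 ± 16.2 in RPM and 34.9 ± 5.74 in kidney cDC2 (n = 5). The T and NK cell genes summed to 59.1 ± 39.5 CPM in kidney cDC2, 73.9 ± 25.1 in CD11bhi YFP+ (n = 5), 33.05 ± 5.95 in CD11bhi YFP- cells (n = 2) and 4.37 ± 0.234 in spleen cDC2 (n = 3). Of 10 plasmacytoid genes 5 were called higher in kidney than in spleen cDC1 (5 adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.149 with an estimated correlation). Klk1, named above among the tubule transcripts, is in this list and in this count. The count is therefore not one of plasmacytoid transcripts alone.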
